A study of Sorghum bicolor with 12 samples.

How the data were processed

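Root RNA came from 6 pools, 3 of bri1-ems72 and 3 of its wild-type sibling WT-ems72, both from the selfed progeny of a second backcross. Per the labels' protocols, embryos were explanted 13 to 17 days after anthesis and grown in vitro at 28 °C for 8 days, at least 6 roots were pooled per replicate, and stranded mRNA libraries were sequenced as paired reads of 100 nt. Per the submitters' processing notes, FastQC 0.11.2, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 1.6.2, edgeR 3.34.1 and R 4.1.1 were used. The genome build, the annotation version and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands and near-identical copies may share reads. The deposited values were raw counts per gene, whole numbers that the authors had not normalized.

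The table's 12 columns carried 6 names, each on 2 columns, which give the pool but not which technical run a column holds. Each pool's 2 columns were therefore summed, and the first-listed and the second-listed columns stood in for run 1 and run 2 in the alternatives that use a single run. Over genes with a summed count of at least 10, the chi-square of the 2 columns of a pool divided by its degrees of freedom was 1.56 to 1.64. This is above counting noise, which gives about 1, and far below the 167.7 to 291.5 for 2 pools of the same genotype. Technical runs were not counted as replicates, and n is the number of pools. The totals of 44357644 to 54629427 counts per pool make counting error small for the named genes, whose lowest count in any pool was 865.

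Differential expression was computed with edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr (23707 genes left, 10422 removed), libraries were scaled with TMM, and genotype was the only term of the quasi-likelihood fit with robust dispersion (glmQLFit, glmQLFTest, two-sided). P-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The common biological coefficient of variation was 0.409. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Gene lists with at least 3 tested members were tested with limma 3.58.1, by camera at an inter-gene correlation of 0.01 and with an estimated correlation, and by fry, adjusted over the 2 lists tested. Single genes were also compared by an exact permutation test over the 20 assignments of 3 pools against 3, for which the smallest two-sided p is 0.1. The fit was tested on 10 simulated data sets with the real genes' means, library sizes and dispersions, each with 200 of 23707 genes changed. It recovered 2.20% of 2-fold, 46.2% of 4-fold, 73.6% of 8-fold and 90.4% of 16-fold changes, and 6.27% of its calls were false. The simulated genes were drawn independently, with no differences between pools shared by many genes. The simulated sets had a median of 1220 genes at unadjusted p below 0.05, against 337 in the real data. These rates therefore need not hold for the real pools.

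The rule for named genes was set before the data were examined. It took BRI1, up to 10 called genes in each direction and called members of 40 fixed lists defined by product text. The table's gene IDs were looked up as written, without conversion to another ID style, and 0 matched the RefSeq gene table at hand. No product text was therefore joined to them, and the 40 lists and the product family enrichment were not applied here. For that case the rule named BRI1 and further genes by IDs known from the literature. Those reported are BRI1 and 6 others, 3 of dhurrin synthesis, 2 of lignin synthesis and ABCB1; 1 further gene, and the list tests that need it, are not reported here. These names come neither from the table nor from the RefSeq gene table, and no coordinates are given.

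The alternatives covered scaling (RLE, total library size), the test (DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test), the filter (none, or at least 1 CPM in 3 pools), a fold threshold, replicate blocks, the 12 libraries as 12 samples, single columns, and leaving out each pool in turn. Distances from BRI1 were not used, as no coordinates were joined to the gene IDs. DESeq2 gave no p for 156 genes with outlying counts, which were left out of its counts.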

Results

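Messenger RNA was sequenced from roots of sorghum (Sorghum bicolor) seedlings of 2 genotypes that segregated in the same backcross population, the mutant bri1-ems72 and its wild-type sibling WT-ems72. BRI1 encodes the cell-surface receptor kinase that binds brassinosteroids, the plant steroid hormones. The comparison asked which root transcripts depend on this receptor. Each genotype had 3 biological replicates, each a pool of at least 6 roots from 8-day-old seedlings raised in vitro from explanted embryos, and each pool was sequenced in 2 technical runs. The table held 34129 genes. After the 2 runs of each pool were summed, the total counts were 45421703, 44357644 and 54629427 in WT-ems72 replicates 1, 2 and 3, and 44896605, 50526498 and 51018644 in bri1-ems72 replicates 1, 2 and 3. A single column held between 21981795 and 27544868 counts.

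BRI1 (Sobic.003G277900) was read in every pool at close levels in both genotypes. Levels are given as CPM, each gene's count scaled to library size. It stood at 83.8 ± 7.68 CPM (SD, n = 3) in WT-ems72 and at 101.5 ± 4.78 CPM (SD, n = 3) in bri1-ems72. The WT-ems72 pools had 88.5, 88.1 and 75.0 CPM and the bri1-ems72 pools 97.9, 99.8 and 106.9 CPM, so that the ranges did not overlap. The log2 fold change of mutant over wild type was 0.28 (SE 0.17, 95% interval -0.12 to 0.67) and did not pass the test over all genes (edgeR quasi-likelihood test, adjusted p = 1.00). An exact two-sided permutation test of the log2 CPM gave p = 0.1, the smallest value that 3 pools against 3 can reach. A point mutation need not alter the level of the transcript, so these values do not check the genotype labels.

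**Figure D1:**
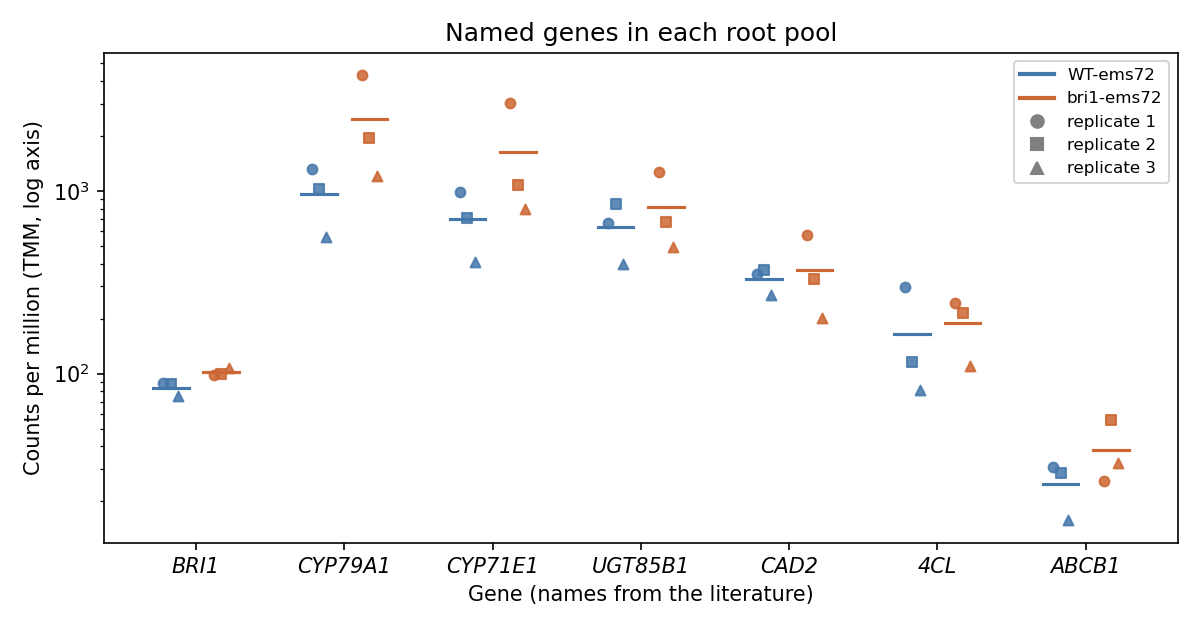
CPM (log axis, TMM-scaled) of 7 genes in the 6 root pools; each point is 1 pool, the marker shape gives its replicate number, the short bar is the mean of 3 pools, and the colour gives the genotype. BRI1 ran from 75.0 to 88.5 in WT-ems72 and from 97.9 to 106.9 in bri1-ems72, and CYP79A1 was 4289 in bri1-ems72 replicate 1 against 1198 in replicate 3.

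Among the 7 named genes were 3 enzymes of dhurrin synthesis, the pathway that makes the cyanogenic glucoside of sorghum. CYP79A1 (Sobic.001G012300), the cytochrome P450 that acts on tyrosine in the first step, had 963 ± 376 CPM (SD, n = 3) in WT-ems72 and 2479 ± 1612 CPM (SD, n = 3) in bri1-ems72, a log2 fold change of 1.36 (SE 0.56). CYP71E1 (Sobic.001G012200), the cytochrome P450 of the following step, had a log2 fold change of 1.21 (SE 0.59). UGT85B1 (Sobic.001G012400), the glucosyltransferase that completes dhurrin, had one of 0.35 (SE 0.45). None of the 3 genes passed the threshold over all genes tested, and 0 of 3 passed when adjusted over the list alone (edgeR, lowest adjusted p = 0.117). As a set the 3 genes were called higher in bri1-ems72 by camera at a preset correlation of 0.01 (adjusted p = 0.000289). The correlation estimated between these genes was 0.943, far above the preset value, so the camera p at 0.01 is too small to rely on. With the estimated correlation the call was lost (camera adjusted p = 0.173), and fry gave an adjusted p of 0.497.

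The dhurrin values differed widely between pools of the same genotype. CYP79A1 had 1308, 1021 and 562 CPM in WT-ems72 replicates 1, 2 and 3 and 4289, 1950 and 1198 CPM in the bri1-ems72 replicates, so bri1-ems72 replicate 3 lay below WT-ems72 replicate 1. The exact two-sided permutation test of its log2 CPM gave p = 0.2. Without bri1-ems72 replicate 1 the log2 fold change of CYP79A1 was 0.69, that of CYP71E1 0.40 and that of UGT85B1 -0.15, below the 0.80 of ABCB1, an auxin transporter gene, in the same fit, and the camera call of the set was lost (adjusted p = 0.212). It was lost too without WT-ems72 replicate 3 (adjusted p = 0.102).

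The 2 genes of lignin synthesis reported here, CAD2 and 4CL, differed between genotypes by less than the spread between pools. CAD2 (Sobic.004G071000), a cinnamyl alcohol dehydrogenase, had 329 ± 53.0 CPM (SD, n = 3) in WT-ems72 and 368 ± 189 CPM (SD, n = 3) in bri1-ems72, a log2 fold change of 0.16 (SE 0.40, 95% interval -0.77 to 1.10). The 4-coumarate:CoA ligase gene 4CL (Sobic.004G062500) had 165 ± 117 CPM and 189 ± 70.3 CPM (SD, n = 3 each), a log2 fold change of 0.20 (SE 0.53, 95% interval -1.07 to 1.46). Neither passed over all genes tested (edgeR, adjusted p = 1.00 for each). Without bri1-ems72 replicate 1 the log2 fold change was -0.32 for CAD2 and -0.048 for 4CL. It was 0.46 for CAD2 without bri1-ems72 replicate 3 and 0.94 for 4CL without WT-ems72 replicate 1.

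ABCB1 (Sobic.007G163800), the auxin efflux transporter known as Dw3, had 25.0 ± 8.09 CPM (SD, n = 3) in WT-ems72 and 38.0 ± 15.5 CPM (SD, n = 3) in bri1-ems72. Its log2 fold change of 0.60 (SE 0.37, 95% interval -0.27 to 1.47) did not pass the test (edgeR, adjusted p = 1.00). It was 0.22 without bri1-ems72 replicate 2, the pool with the highest value (55.4 CPM).

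Across the genome no gene passed the threshold. Of 23707 genes tested with edgeR, 0 were higher and 0 lower in bri1-ems72 at an adjusted p below 0.05. At an unadjusted p below 0.05 there were 337 genes (1.42%), of which 275 were higher and 62 lower in bri1-ems72, where 5% of the tested genes is 1185. Without bri1-ems72 replicate 3 there were 509. The share that was higher went from 81.6% to 57.6% without WT-ems72 replicate 2. DESeq2 called 3 genes higher and 2 lower, edgeR's likelihood ratio test 1 and 1, and limma-voom 0 and 0. The 95% interval of the log2 fold change lay within ±1 for 12117 genes (51.1%). For each of those genes taken singly it left out a change of more than 2-fold, and for the others it did not. The intervals are not adjusted over genes, so some of them may miss the true value. They bound the difference between the labelled groups only.

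The 5 DESeq2 calls were genes without names here, and they were singled out after their values were seen. IDs are given for 2 in each direction. Sobic.007G164750 had 0.299 ± 0.0242 CPM (SD, n = 3) in WT-ems72 and 8.53 ± 6.66 CPM (SD, n = 3) in bri1-ems72, a DESeq2 log2 fold change of 4.83 (SE 0.72, adjusted p = 5.55e-07), and was also called by the likelihood ratio test. Sobic.006G117500 had 22.2 ± 3.93 and 52.7 ± 10.1 CPM (SD, n = 3 each) and a log2 fold change of 1.25 (SE 0.28, DESeq2 adjusted p = 0.0485). The other gene called higher had 1.13 ± 0.144 and 3.93 ± 1.24 CPM (SD, n = 3 each) and a log2 fold change of 1.80 (SE 0.38, DESeq2 adjusted p = 0.0339). In these 3 genes each bri1-ems72 pool lay above each WT-ems72 pool. For a gene not picked by its values, chance gives such a separation in 10% of cases counting both directions. These genes were picked by their difference between the same pools, so the separation adds no support. Sobic.004G321200 was lower in the mutant, at 0.869 ± 0.223 CPM against 3.39 ± 1.07 CPM (SD, n = 3 each), with a log2 fold change of -1.97 (SE 0.43, DESeq2 adjusted p = 0.0339). Its pools separated too, with at most 1.03 CPM in bri1-ems72 and at least 2.64 CPM in WT-ems72. Sobic.003G099900 was called lower (DESeq2 adjusted p = 0.0485), but WT-ems72 replicate 3 had 0.02 CPM, within the 0 to 0.08 CPM of the mutant pools, and edgeR's filter left it out. The edgeR quasi-likelihood test gave an adjusted p of 1.00 for the other 4.

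Pools of the same genotype were no closer to each other than pools of different genotypes. Pearson's r of log2 CPM, taken across genes, which are not independent replicates, was 0.924 to 0.949 for the 6 pairs of pools within a genotype and 0.928 to 0.969 for the 9 pairs between genotypes. The first principal component held 34.1% of the variance and the second 28.4%, and neither separated the genotypes. Over the 12 single libraries the first held 31.7% and the second 26.8%. The 2 technical runs of a pool had r from 0.992 to 0.994, above every pair of libraries from different pools (at most 0.967).

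**Figure D2:**
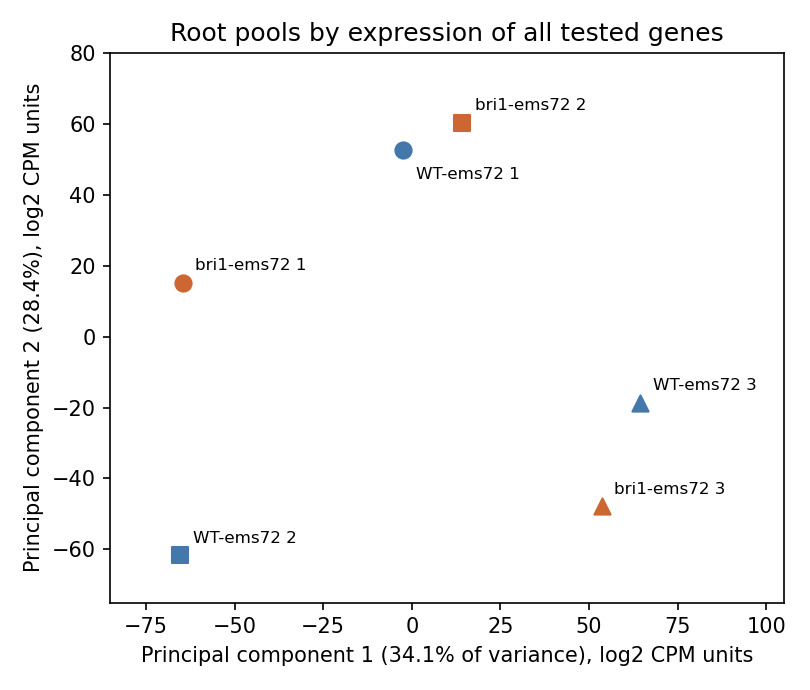
Scores of the 6 root pools on the first and second principal components of log2 CPM over the 23707 tested genes; each point is 1 pool, labelled with its genotype and replicate number and coloured by genotype. On the first component WT-ems72 ran from -65.3 to 64.5 and bri1-ems72 from -64.6 to 53.6, so the genotypes overlapped.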

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

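The block of pairs completed from unmatched titles and the counts and shares at unadjusted p were chosen after the data were seen, and the other alternatives before. Of 20 alternatives, 17 gave 0 genes higher and 17 gave 0 lower. Among these the fold threshold could give nothing else, as it only narrows the main fit's 0 calls. The exceptions were DESeq2 (3 higher, 2 lower), edgeR's likelihood ratio test (1 and 1) and the 12 libraries as 12 samples (47 and 6), which counts technical runs as replicates. DESeq2 and the 12 libraries shared 4 genes. The cause of the DESeq2 and likelihood ratio differences was not tested. BRI1 kept its sign under its 19 alternatives (log2 fold change 0.20 to 0.34), as did CYP79A1 (0.69 to 1.70), CYP71E1 and ABCB1, and none of the 7 named genes was called. Leaving out each pool in turn gave log2 fold changes of -0.15 to 0.61 for UGT85B1, -0.32 to 0.46 for CAD2 and -0.13 to 0.94 for 4CL. It gave camera adjusted p of 6.58e-06 to 0.212 for the dhurrin list. The dhurrin call was lost with an estimated correlation (0.173) and with fry (0.497). The replicate block by description number gave 0 and 0 calls and a BRI1 log2 fold change of 0.28. Its pairs deviated from their genotype means with correlations of 0.04, -0.23 and 0.40, so the numbers were not taken to pair the pools. The replicate block by title number gave 0 and 0 calls and 1311 genes at unadjusted p below 0.05. The cause of that count was not tested. The block turned CAD2 (-0.25) and 4CL (-0.024). WT-ems72 replicate 2 and bri1-ems72 replicate 1, whose title numbers match no other pool, do not enter its genotype contrast. Between these 2 pools the log2 difference was 0.65 for CAD2 and 1.07 for 4CL. The sign is set by the matched pairs, with -0.1 and -0.41 for CAD2 and -0.48 and 0.44 for 4CL. With the unmatched titles as a further pair, 645 genes had unadjusted p below 0.05 and 0 were called. List tests were not run with DESeq2 or the likelihood ratio test. The distance windows around BRI1 and the product family enrichment were not run, for want of coordinates, product text and called genes.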

Other observations

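The tests of the other splits, of the title numbers, of the genes next to BRI1 and of the genes read in some pools only were chosen after the results were seen; those of library scaling and of leaving out each pool were set after the share they test was seen and before their own results were. Some genes were read in some pools and not in others. With a pool counted as positive above 20% and as negative below 2% of the gene's highest CPM, and a highest CPM of at least 1, 30 genes fell cleanly into positive and negative pools. For 0 of them did the pattern separate the genotypes, but few patterns had 3 positive and 3 negative pools, so this count decides little. The cut-offs left out Sobic.007G164750, at 0.27 to 0.32 CPM in the WT-ems72 pools and 1.71 to 15.01 CPM in the bri1-ems72 pools. For 6 genes bri1-ems72 replicate 2 was the only positive pool, and for 6 others the positive pools were WT-ems72 replicate 1 and bri1-ems72 replicate 1. Of those 6, 4 carried the number of chromosome 2 in their IDs, and WT-ems72 replicate 1 had 0.21 to 0.42 of the level of bri1-ems72 replicate 1. Genes with the same pattern carried the same chromosome number in 13 pairs, against a mean of 4.31 pairs when patterns were shuffled over the genes (permutation p = 0.00076, 100000 shuffles). A candidate explanation is chromosome segments that still segregated in the backcross and entered some pools; neighbouring copies regulated together, and reads shared between them, were not tested and stay open.

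Genotype accounted for little of the variation between pools, and mislabelled pools or pools of mixed genotype, for which no value here is a check, stay open as explanations. Fewer genes than 5% had an unadjusted p below 0.05 (337 of 23707), and genotype held 11.3% of the variance of log2 CPM against 11.8% to 28.4% for the other 9 splits of the 6 pools into 3 and 3. Of those splits, 8 gave more genes at unadjusted p below 0.05, so larger differences between pools ran across the genotypes. The highest gave 3397, with WT-ems72 replicate 1 and bri1-ems72 replicates 1 and 2 on the same side. It was picked as the highest of 9, and the 10 splits average 20% of the variance by construction. These counts therefore do not show a structure beyond ordinary differences between pools. With the 12 libraries as 12 samples, the genotype split called 53 genes and the highest other split 5431. All 10 splits, the real one included, gave 0 calls from the summed counts, and 10 splits are too few for a share under 5%. A candidate source of these differences is a shared origin of pools with the same number in their titles. The 2 such pairs deviated from their genotype means with correlations of 0.39 and 0.40, above the other 7 pairs across genotypes (at most 0.24). Of 18 ways to choose 2 disjoint pairs, 1 had both correlations as high, and 18 are too few for a share under 5%. The pair at 0.40, replicate 3 of each genotype, also shares its description number. The labels do not say what the title number marks. With the title number as a block, which rests on those 2 pairs, 1311 genes had an unadjusted p below 0.05, above the 1185 that make 5%. With the unmatched pools as a further pair there were 645 and with the description number as a block 419, both below 1185. In each block 0 genes were called. The blocks leave fewer residual degrees of freedom than the main fit, and the title number leaves the fewest. Their counts are therefore not directly comparable with its 337.

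Most of the genes at unadjusted p below 0.05 were higher in bri1-ems72 (275 of 337, 81.6%). The share was 79.4% with total library size and 81.4% with RLE, but these scalings moved the median log2 fold change of all genes only from -0.012 to -0.022 and -0.013, too little to test library scaling, which stays open. Leaving out WT-ems72 replicate 2 brought the share to 57.6% of 413 genes, and leaving out bri1-ems72 replicate 3 to 60.3% of 509 genes. The larger share stayed on the same side in each case, and whether the unevenness rests on single pools stays open. In both fits more genes were lower than the 62 of the main fit. The fall in share therefore does not show that the excess of higher genes rests on single pools. It was 63.3% with the title number as a block (1311 genes) and 63.0% with the 12 libraries as 12 samples (2090 genes). The real split was the most uneven of the 10 (1 of 10 splits as uneven, highest other 67.0%), and 10 splits are too few for a share under 5%. A response to the mutation stays open and untested.

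Among the 200 tested genes next to BRI1 in the order of the gene IDs, 100 on each side, 2 had an unadjusted p below 0.05 (1.00%), against 335 of the other 23506 (1.43%; one-sided Fisher's exact test p = 0.78).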
